A study of Mus musculus with 8 samples.

How the data were processed

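RNA from sorted mouse lung macrophages was sequenced in 8 libraries, 4 ZsGreen-positive and 4 ZsGreen-negative, collected 24 h after intravenous injection of ZsGreen-expressing B16-F10 melanoma cells. Per the labels' protocols, RNA was isolated with a column kit for small samples (PicoPure), libraries were made with a Nugen Ovation kit, and single-end reads of 50 bp were sequenced on an Illumina HiSeq. Per the submitters' processing notes, STAR 2.4.2a, DESeq2 and the mouse build GRCm38 were used; their roles, the gene annotation, the counting program and its strand setting are not given in the sources used here. The deposited values are whole-number counts of reads per Ensembl gene, not normalized, in 43432 rows per library, per the file headers and the values themselves, whose totals differ between libraries. Amplified libraries without molecular identifiers count reads, not molecules, so intervals and limits of detection given here cover counting error only. The ZsGreen transcript itself was not analysed here.

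Gene symbols came from GENCODE M21 (GRCm38), which matched 42462 of the 43432 identifiers. Positions and overlapping genes came from the same annotation, whose build has the name given in the processing notes; that the counting used this release is not known. Samples were grouped by the cell population named in their titles. The totals ranged from 10229004 to 59817994 counts per library. Chi-square tests of counts over genes found each pair of libraries of one group far apart (at least 304 per degree of freedom), which argues only against one library being listed more than once. Repeat libraries of 1 sample would differ too, so each library counted as 1 replicate on the labels alone. The labels call them biological replicates and the animals matched in age and sex, without saying that they came from separate mice, so the p-values measure the spread between these libraries.

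The main test was edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood functions glmQLFit and glmQLFTest, TMM scaling, filterByExpr at its defaults (minimum count 10), group as the only term and Benjamini-Hochberg adjustment over the 9257 genes kept, with a threshold of 0.05. Log2 fold changes are ZsGreen-positive minus ZsGreen-negative; their SE was approximated as the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD. The spread between replicates was wide: the common dispersion was 1.75, a biological coefficient of variation of 132%. The median Spearman correlation between libraries of one group was 0.659. ZsGreen-negative replicate 1 had correlations of 0.733, 0.681, 0.635 and 0.656 with ZsGreen-positive replicates 1 to 4. With ZsGreen-negative replicates 2 to 4 its correlations were 0.664, 0.578 and 0.597.

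Gene lists of cell types and processes were fixed before the data were examined: 29 tested lists, and 2 for reading the sort gate and sex-linked genes. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists, and again with the correlation estimated per list; only the conventional dendritic cell, interstitial macrophage and lysosome lists passed both. Camera compares the members of a list with the other tested genes, so its directions are relative to those genes. Per list, members past 0.05 were counted over all genes and adjusted over the list alone. Several genes stand on more than 1 list, as Lpl does. The shares of counts in mitochondrially encoded and in melanocyte lineage genes, and 6 other library measures, were compared by exact two-sided permutation tests over 70 arrangements. Detection was compared after thinning each library to 10000000 counts. A gene counted as lost in a library when its median in the others was at least 50 CPM and its own level below 1 CPM.

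Genes were named by a rule fixed in advance. It took up to 10 higher and 10 lower genes past the threshold with the largest fold changes, non-overlapping groups and at least 10 CPM in the higher group, skipping predicted models and clones. It also took up to 4 members per list, or the 2 with the smallest p where no member passed and the list did not, and all members of the sort gate and sex-linked lists with 5 pigment genes. Genes outside the rule, which are Hsph1 and those of the closing part, were chosen after their values were seen.

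The fits were tested on simulated counts with the real genes' means, dispersions and library sizes and 200 changed genes in each of 5 simulations of this comparison (9257 genes). edgeR recovered 2.69% of genes changed by a log2 fold of 2, 30.7% of those changed by 4 and 87.3% of those changed by 8, and called 0.0552% of unchanged genes. DESeq2 recovered 10.7%, 54.3% and 87.9%, and called 0.969% of unchanged genes. These were 439 unchanged genes, beside 36, 182 and 290 changed genes by size of fold, so many of its calls were false. With edgeR they were 25, beside 9, 103 and 288. A recovery needed the right sign in edgeR, but sign was not checked in DESeq2. When the lysosome list was shifted by a log2 fold of 1, camera with the preset called it in 10 of 10 simulations. With an estimated correlation camera called it in 2 of 10. With the preset it called 0 of 260 unshifted lists. The simulated genes varied independently, while the correlation estimated in the real lists reached 0.344 (alveolar macrophage). These runs therefore do not measure how often the preset makes false calls in these data.

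The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE, upper-quartile and library-size scaling, no filter and a filter of 1 CPM in 4 libraries, the replicate number as a block, each library left out in turn, a threshold of 0.01, glmTreat against a log2 fold of 1, and fry. After the data were examined, fits without the replicate 1 libraries, without ZsGreen-negative replicates 3 and 4, with replicate 1 against the rest as a term, with robust dispersions and without mitochondrially encoded genes were added.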

Results

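Lung cells labelled as macrophages that had ingested metastatic material were compared with cells of the same sort gate that lacked the fluorescence of the tumour cells. C57BL/6 mice received B16-F10 cells, a mouse melanoma line that carried the green fluorescent protein ZsGreen, into a vein, and lung cells were collected 24 h later. The sorted cells were live CD45+ cells without lymphocyte, neutrophil, NK cell or SiglecF markers that stained for CD11c and MHC class II and lacked CD24. They were divided by ZsGreen fluorescence into a ZsGreen-positive group of 4 libraries and a ZsGreen-negative group of 4 libraries, called biological replicates 1 to 4 in each group. A lack of fluorescence at 24 h does not show that a cell had taken up no tumour material. The labels do not say whether a replicate was 1 mouse or a pool, nor whether equal numbers in both groups mark the same animals. The deposited values were raw counts for 43432 Ensembl genes. The ZsGreen-positive libraries held 59817994, 24637063, 27899300 and 19671950 counts (replicates 1 to 4) and the ZsGreen-negative libraries 10229004, 24593363, 13809674 and 25764181.

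Levels of the genes behind the sort were as follows. Ptprc, which encodes CD45, averaged 1965 ± 232 CPM (TMM-scaled; SD, n = 4) in ZsGreen-positive and 3041 ± 608 in ZsGreen-negative libraries, Itgax, which encodes CD11c, 551 ± 105 and 544 ± 289, and the MHC class II gene H2-Ab1 4380.3 ± 720.0 and 6503 ± 2028. None of the 3 passed the test between groups in edgeR (adjusted p = 0.610, 0.997 and 0.659). Cd3e, Thy1 and Ly6g, which mark T cells and neutrophils, had 0 counts in all 8 libraries, and 3 counts, the limit that a count of 0 allows, correspond to between 0.0502 and 0.293 CPM of the unscaled totals. Siglecf and the NK cell gene Klrb1c stayed below 1 CPM except in ZsGreen-positive replicate 4 for Siglecf (18.5 CPM) and in ZsGreen-positive replicate 3 and ZsGreen-negative replicate 2 for Klrb1c (18.1 and 30.6 CPM). Cd24a, whose product was used to exclude cells, averaged 48.4 ± 19.6 and 108 ± 30.9 CPM (adjusted p = 0.729). The B cell gene Cd19 had 1 count in ZsGreen-negative replicate 4 and 0 in the other 7 libraries. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had counts in all 8 libraries and none differed between groups past the threshold (adjusted p = 0.994, 0.978, 0.748 and 0.850), while Xist, which is transcribed from the inactive X chromosome, had 297 counts in ZsGreen-negative replicate 2 and at most 4 in each of the others.

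Mitochondrially encoded genes took 38.7% ± 4.48 of the counts in ZsGreen-positive and 43.3% ± 7.49 in ZsGreen-negative libraries (SD, n = 4 each; exact two-sided permutation p = 0.314; Benjamini-Hochberg adjusted p = 0.314 over 8 library measures). Most of these counts came from the mitochondrial ribosomal RNAs, at 34.1% ± 4.27 and 38.9% ± 6.04. Thinned to 10000000 counts, ZsGreen-positive libraries detected 11324 ± 463 genes and ZsGreen-negative libraries 10193 ± 1523 (exact permutation p = 0.257). ZsGreen-negative replicates 3 and 4 detected the fewest, 8991 and 9087, and 2.98% and 2.80% of the genes that were abundant in the other libraries fell below 1 CPM there, against at most 0.523% in the other 6 libraries. Heat shock transcripts divided the libraries by replicate number: Hsph1, a heat shock chaperone gene, stood at 56.7 and 96.2 CPM in the replicate 1 libraries of the ZsGreen-positive and ZsGreen-negative groups and between 1106 and 2993 CPM in the other 6 libraries.

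**Figure D1:**
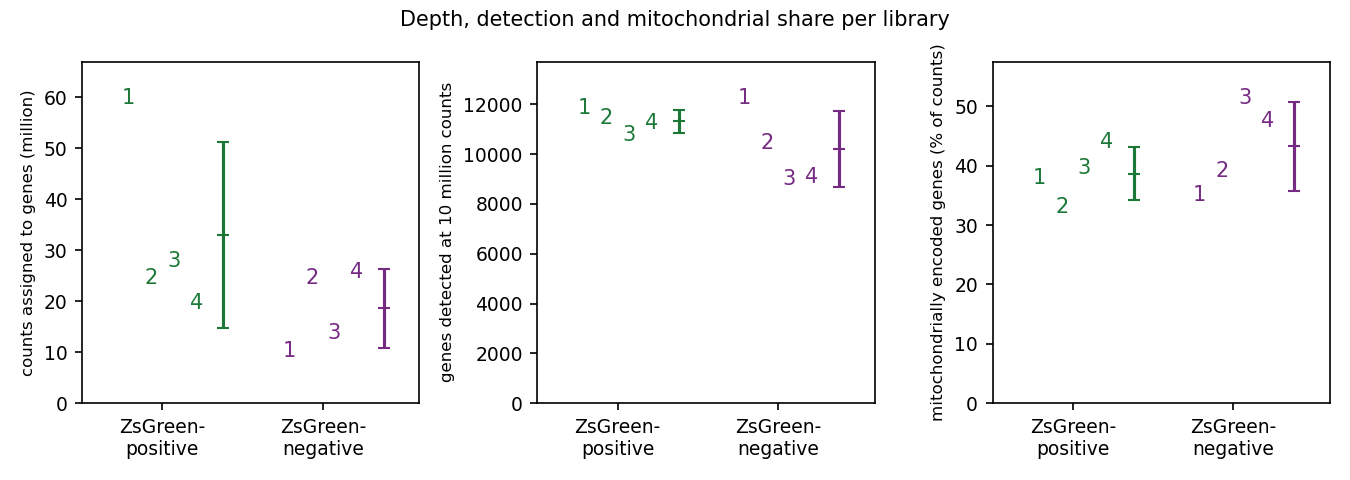
Total counts assigned to genes (left), genes detected after thinning each library to 10000000 counts (middle) and percent of counts in mitochondrially encoded genes (right), for ZsGreen-positive and ZsGreen-negative libraries. Digits are replicate numbers, and the bars give the mean and SD of 4 libraries. ZsGreen-negative replicates 3 and 4 have the fewest genes detected (8991 and 9087) and the highest mitochondrial shares (51.4% and 47.6%).

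The comparison of ZsGreen-positive with ZsGreen-negative cells addressed which transcripts distinguish macrophages that hold tumour material. Of the 9257 genes tested, 5 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. Vcam1, which encodes an adhesion molecule bound by integrins, was higher in ZsGreen-positive libraries, at 224 ± 89.6 against 0.692 ± 0.437 CPM (SD, n = 4; log2 fold change 8.38 ± 0.91 SE, adjusted p = 0.00104). Ctsb, which encodes the lysosomal protease cathepsin B, was also higher, at 2354 ± 363 against 471 ± 201 CPM (log2 fold change 2.32 ± 0.38, adjusted p = 0.0378). Cd209a, a C-type lectin gene of the DC-SIGN family, was lower, at 6.26 ± 4.17 against 340 ± 145 CPM (log2 fold change -5.76 ± 0.74, adjusted p = 0.00462). Kit, a receptor tyrosine kinase gene, was lower at 0.303 ± 0.218 against 194 ± 228 CPM (log2 fold change -9.33 ± 1.43, adjusted p = 0.0265), and its counts in ZsGreen-positive libraries were between 4 and 12. Mfsd6, which encodes a membrane transporter-like protein, was lower at 12.96 ± 9.75 against 304 ± 130 CPM (log2 fold change -4.55 ± 0.75, adjusted p = 0.0378). For each of the 5 genes, the 4 libraries of one group all lay above the 4 of the other.

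In GRCm38 with the GENCODE M21 annotation, the 5 are protein-coding genes. Vcam1 (ENSMUSG00000027962) lies on chromosome 3 from 116109949 to 116129688, Ctsb (ENSMUSG00000021939) on chromosome 14 from 63122462 to 63145923, and Cd209a (ENSMUSG00000031494) on chromosome 8 from 3743397 to 3748984. Kit (ENSMUSG00000005672) lies on chromosome 5 from 75574916 to 75656722 and Mfsd6 (ENSMUSG00000041439) on chromosome 1 from 52656286 to 52727462. Vcam1 overlaps Gm43109 and Ctsb overlaps Fdft1, both on the opposite strand, and Mfsd6 overlaps Gm29670. Whether the counting used strand is not given in the sources used here, so reads of such overlapping pairs may have been divided between them or left out.

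The number of genes past the threshold depended on the tool and on single libraries. DESeq2 called 519 genes, 330 higher and 189 lower, among them all 5 edgeR genes, and limma-voom called 10, among them 3 of the 5. With upper-quartile scaling edgeR called 4 higher and 3 lower genes, and with library size alone 5 higher and 2 lower, against 2 higher and 3 lower with TMM. Those scalings shifted the median log2 fold change of all genes by 0.16 and 0.38, and RLE scaling by -0.16, from -0.11 with TMM. Vcam1 and Cd209a passed without each of the 8 libraries in turn. Ctsb and Mfsd6 passed without ZsGreen-negative replicate 3 and lost the call without any other single library, with adjusted p between 0.0776 and 0.208 for Ctsb and between 0.0509 and 0.208 for Mfsd6. Kit lost it without ZsGreen-negative replicate 4 or without any 1 ZsGreen-positive library, with adjusted p between 0.0901 and 0.146. Without ZsGreen-negative replicate 4, where Kit stood at 524.6 CPM against 3.837 to 129.9 in the other 3, its log2 fold change moved to -8.11, and limma-voom gave -7.37 (adjusted p = 0.183). Without ZsGreen-negative replicates 3 and 4 it was -7.64 (0.163). Mfsd6 moved to -5.17, with a mean of 8.38 CPM, without ZsGreen-positive replicate 2, and it lost the call with RLE scaling (0.0624) and library size alone (0.0857), as Ctsb did with RLE scaling (0.277). Among genes named below that missed the edgeR threshold, DESeq2 passed Mertk, Btla, Flt3, Nr4a1, Eno3, Cdh1, Ctsd, Acp5, Acp2, Cxcl9, Nfkbia, Tnfaip3, Traf1, Ccl22, Cox5a, Slc40a1 and Spic. In the simulations DESeq2 called more unchanged genes than edgeR (0.969% against 0.0552%), so these passes carry less weight. Without a filter on low counts edgeR passed Mki67, Mertk, Mafb, Btla, Flt3, Fn1, Nr4a1, Cdh1, Scgb1a1, Ctsd, Igf1, Cxcl9, Nfkbia and Slc40a1, and limma-voom passed Flt3. In replicates 2 to 4 alone, 5 genes passed, 3 of them shared with the 5 above: Vcam1 (adjusted p = 0.0279), Cd209a and Kit (0.00929 each).

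**Figure D2:**
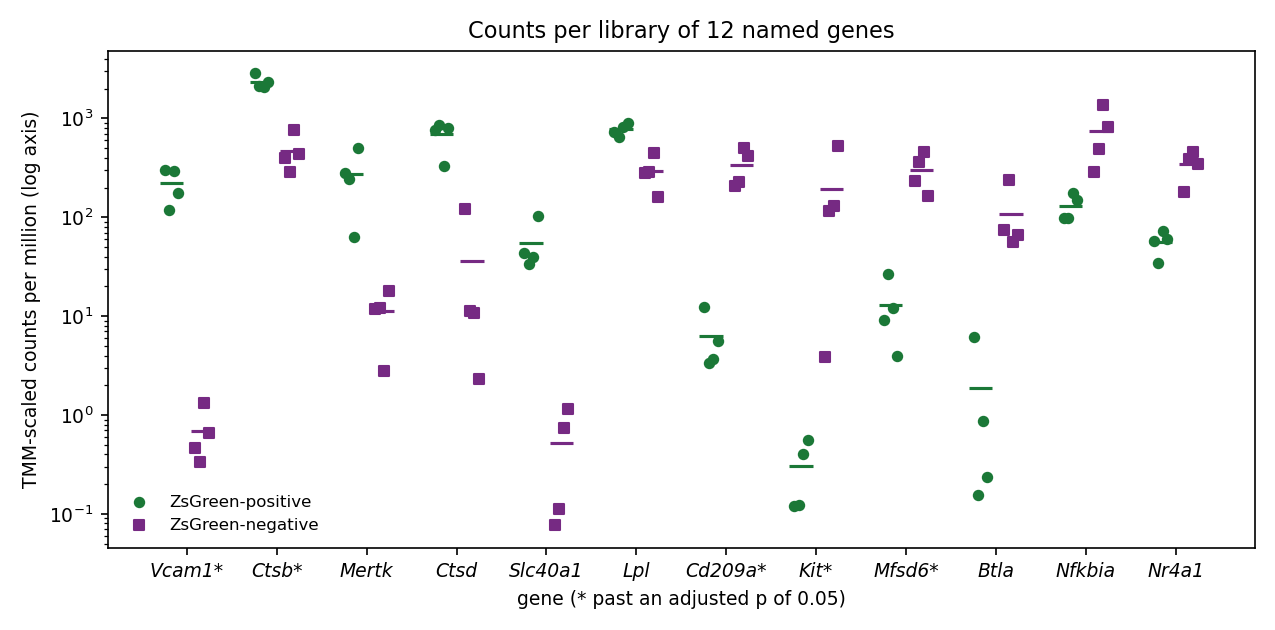
TMM-scaled CPM, on a log axis, of 12 genes in each library. Circles are the 4 ZsGreen-positive and squares the 4 ZsGreen-negative libraries, horizontal lines are group means, and asterisks mark the 5 genes past an adjusted p of 0.05. In all 12 genes the groups do not overlap, and Vcam1 lies between 119.5 and 299.6 CPM in ZsGreen-positive against at most 1.32 CPM in ZsGreen-negative libraries.

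Conventional dendritic cell genes were lower as a group in ZsGreen-positive libraries. Of 13 measured members, 2 (Cd209a and Kit) were lower past the threshold over all genes, and 9 were lower adjusted over the list alone. The median log2 fold change was -3.41, and the list passed camera (adjusted p = 2.48e-11 over 29 lists; adjusted p = 0.00795 with an estimated correlation). Flt3, the receptor for a growth factor of dendritic cells, averaged 0.250 ± 0.435 against 48.4 ± 29.4 CPM, and Btla, an inhibitory receptor gene, 1.87 ± 2.91 against 109 ± 87.3 CPM. Both lay lower in 4 of 4 ZsGreen-positive libraries and neither passed over all genes (adjusted p = 0.285 and 0.241). The ZsGreen-positive mean of Btla was 0.422 CPM without replicate 1 (6.21 CPM) and that of Flt3 0.0337 without replicate 2 (0.8995 CPM), and the ZsGreen-negative mean of Btla was 65.8 CPM without replicate 2 (239.8 CPM). The list passed without ZsGreen-negative replicates 3 and 4 (adjusted p = 1.27e-05) and in replicates 2 to 4 alone (4.60e-09).

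Interstitial macrophage genes were higher as a group. Of 17 measured members, 15 had a fold above 0 and 9 lay higher in every ZsGreen-positive than in every ZsGreen-negative library. No member passed over all genes, and 3 were higher adjusted over the list alone. The median log2 fold change was 1.62 (camera adjusted p = 7.61e-05; adjusted p = 0.0306 with an estimated correlation). Mertk, a receptor kinase for apoptotic cell uptake, averaged 273 ± 180 against 11.2 ± 6.28 CPM (adjusted p = 0.0736). Mertk passed with DESeq2 (adjusted p = 6.74e-05), upper-quartile scaling (0.0382), library size alone (0.0397), no filter on low counts (2.43e-05), robust dispersions (0.0411) and without ZsGreen-positive replicate 3 (0.0468). Mafb, a macrophage transcription factor gene, averaged 712 ± 88.9 against 183 ± 134, the complement gene C1qb 514 ± 96.9 against 167 ± 87.3, and the lipoprotein gene Apoe 93.8 ± 26.8 against 10.7 ± 11.2 CPM. Their adjusted p over all genes were 0.301, 0.326 and 0.424, and the ZsGreen-negative mean of Apoe was 5.63 CPM without replicate 1.

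Lysosome and phagosome genes were also higher as a group. All 45 members were measured, 37 with a fold above 0 and 8 below. Ctsb was higher past the threshold over all genes, and 7 members were higher adjusted over the list alone. The median log2 fold change was 1.24 (camera adjusted p = 2.53e-06; adjusted p = 0.0306 with an estimated correlation). Ctsd, the cathepsin D gene, averaged 691 ± 244 against 36.2 ± 56.3 CPM (adjusted p = 0.241), and the acid phosphatase genes Acp5 and Acp2 44.4 ± 30.0 against 0.956 ± 1.23 and 154 ± 51.2 against 17.3 ± 17.02 CPM (0.293 and 0.301). The ZsGreen-negative mean of Acp5 was 0.345 CPM without replicate 2 and that of Acp2 9.17 CPM without replicate 1. Ctsd stood at 120.5 CPM in ZsGreen-negative replicate 1 and at most 11.3 CPM in the other 3, and without that library it passed (log2 fold change 6.42, adjusted p = 0.00243). It also passed with all 8 libraries in DESeq2 (adjusted p = 0.0168) and in edgeR with replicate 1 as a term (0.0240).

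Further lists that were higher passed camera only with the preset correlation. Of these, the NRF2, haem and iron list and the TREM2 list also passed with fry (adjusted p = 0.0185 and 0.00273). NRF2, haem and iron genes had a median log2 fold change of 1.41 over 21 members, 1 of them higher adjusted over the list alone (camera adjusted p = 5.51e-05; adjusted p = 0.139 with an estimated correlation). Slc40a1, which encodes the iron exporter ferroportin, averaged 54.7 ± 32.0 against 0.517 ± 0.517 CPM (adjusted p = 0.209; 0.0489 without ZsGreen-negative replicates 3 and 4). Spic, a transcription factor gene of iron-recycling macrophages, averaged 16.7 ± 9.75 against 0.382 ± 0.670 CPM, and Hmox1, the haem-degrading enzyme gene, 78.0 ± 39.1 against 12.5 ± 9.34 CPM (adjusted p = 0.535 and 0.536). The ZsGreen-negative mean of Spic was 0.0488 CPM without replicate 1 and that of Slc40a1 0.307 CPM without replicate 4. Cholesterol efflux and lipid handling genes had a median of 1.05 over 20 members, 18 with a fold above 0 and 0 past the threshold by either adjustment (camera adjusted p = 0.00164; adjusted p = 0.318 with an estimated correlation). Lpl, the lipoprotein lipase gene, averaged 777 ± 105 against 294 ± 117 CPM, Nr1h3, which encodes the sterol receptor LXR-alpha, 67.3 ± 18.8 against 6.05 ± 7.08, and the sterol exporter gene Abcg1 111 ± 35.4 against 27.2 ± 22.4 (adjusted p = 0.309, 0.446 and 0.598). The ZsGreen-negative mean of Nr1h3 was 3.01 CPM without replicate 1 and that of Abcg1 17.7 CPM without replicate 2.

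The TREM2 and lipid-associated macrophage list had a median log2 fold change of 0.44 over 17 members, with 0 past the threshold over all genes and 5 higher adjusted over the list alone (camera adjusted p = 0.0217; adjusted p = 0.172 with an estimated correlation). Igf1, a growth factor gene on that list, averaged 286 ± 101 against 15.2 ± 24.6 CPM (adjusted p = 0.288). It stood at 51.8 CPM in ZsGreen-negative replicate 3 and at most 7.21 CPM in the other 3, and without that library it passed (log2 fold change 6.63, adjusted p = 0.0198). Oxidative phosphorylation genes had a median of 1.06 over 32 members, 24 with a fold above 0 and 0 past the threshold by either adjustment (camera adjusted p = 0.00753; adjusted p = 0.443 with an estimated correlation). Cox5a, a subunit of cytochrome c oxidase, averaged 9.30 ± 3.39 against 0.177 ± 0.114 CPM, and the ATP synthase gene Atp5c1 191 ± 113 against 69.8 ± 61.2 (adjusted p = 0.413 and 0.717), the latter 45.1 CPM without ZsGreen-negative replicate 4. The TREM2 list lost its call without ZsGreen-negative replicate 1 or 2 (adjusted p = 0.123 and 0.102) and in replicates 2 to 4 alone (0.146). The oxidative phosphorylation list lost it without ZsGreen-negative replicate 3 (0.0823) and without ZsGreen-negative replicates 3 and 4 (0.138).

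The NF-kB inflammatory and the immediate early lists passed in the lower direction with the preset correlation alone. Their mean log2 CPM differed by -0.30 and -0.52 between the groups. Relative to all tested genes the differences were -1.01 and -1.23, so each call rests in part on the level of the other genes. The NF-kB list had a median log2 fold change of -1.05 over 26 members, with 0 past the threshold over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.00255; adjusted p = 0.0812 with an estimated correlation). Nfkbia, the NF-kB inhibitor gene, averaged 131 ± 38.6 against 739 ± 467 CPM, Tnfaip3, another inhibitor of the pathway, 149 ± 32.6 against 557 ± 162, and Traf1, a signalling adaptor gene, 18.5 ± 13.3 against 150 ± 76.6 (adjusted p = 0.189, 0.252 and 0.293). The dissociation and immediate early list had a median of -0.92 over 27 members, 23 with a fold below 0 and 1 lower adjusted over the list alone (camera adjusted p = 0.000130; adjusted p = 0.146 with an estimated correlation). Among them, Nr4a1, an orphan nuclear receptor gene, averaged 56.6 ± 16.4 against 343 ± 117, Btg2 103 ± 36.3 against 290 ± 123, and Zfp36, which encodes an RNA-destabilising protein, 532 ± 142 against 1020.1 ± 147 CPM (adjusted p = 0.189, 0.465 and 0.519). The NF-kB and immediate early lists each had an adjusted p of 0.0614 without ZsGreen-negative replicates 3 and 4, the 2 libraries with the fewest genes.

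Cell cycle genes were lower as a group, with a median log2 fold change of -1.73 over 18 members, 0 past the threshold over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00584; adjusted p = 0.0828 with an estimated correlation). Mki67, a marker of cycling cells, averaged 230 ± 195 against 1348 ± 979 CPM, and Top2a, a topoisomerase of dividing cells, 45.6 ± 25.5 against 228 ± 233 (adjusted p = 0.288 and 0.332). Top2a stood at 577.5 CPM in ZsGreen-negative replicate 3 and between 105 and 119.2 CPM in the other 3, and its log2 fold change of -2.32 became -1.29 without that library. The ZsGreen-positive mean of Mki67 was 142 CPM without replicate 3. The list had an adjusted p of 0.0614 without ZsGreen-negative replicates 3 and 4. Its mean log2 CPM differed by -0.86 between the groups and by -1.57 relative to all tested genes.

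The lists of 2 other cell types also passed in the lower direction with the preset correlation alone, with 0 members past the threshold over all genes. Nonclassical monocyte genes had a median log2 fold change of -1.15 over 12 members, 1 lower adjusted over the list alone (camera adjusted p = 0.0309; adjusted p = 0.318 with an estimated correlation); Eno3 averaged 8.78 ± 7.81 against 76.7 ± 71.7 CPM (adjusted p = 0.424). Eno3 stood at 182.9 CPM in ZsGreen-negative replicate 3, and that group averaged 41.3 CPM without it; the ZsGreen-positive mean was 5.12 CPM without replicate 2. The nonclassical monocyte list lost its call without ZsGreen-positive replicate 3 or 4 (0.103 and 0.0799) and without ZsGreen-negative replicate 1 or 2 (0.228 and 0.0994). It also lost it in replicates 2 to 4 alone (0.112), with replicate 1 as a term (0.0592), with the replicate block (0.0817) and with fry (0.345). Its mean log2 CPM differed by -0.30 between the groups and by -1.01 relative to all tested genes. Lung epithelium genes had a median of -2.44 over 4 measured members, 1 lower adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.277 with an estimated correlation). Their mean log2 CPM differed by -1.66 between the groups and by -2.37 relative to all tested genes. Cdh1, the E-cadherin gene, which some dendritic cells also express, averaged 1.82 ± 1.32 against 70.1 ± 70.7 CPM (adjusted p = 0.285). The ZsGreen-negative libraries held Cdh1 at 20.26, 6.214, 95.7 and 158.3 CPM (replicates 1 to 4), with a mean of 40.7 without replicate 4, and without replicates 3 and 4 its log2 fold change of -5.27 became -2.83 (adjusted p = 0.721). Scgb1a1, a club cell gene, reached 889.5 CPM in ZsGreen-negative replicate 3 and at most 1.46 CPM in the other 3 ZsGreen-negative libraries. In ZsGreen-positive libraries Scgb1a1 stood at 0.1475, 63.95, 23.97 and 0.2803 CPM (replicates 1 to 4), and its log2 fold change of -3.33 turned to 5.25 without ZsGreen-negative replicate 3, short of the threshold in both fits. The epithelial list lost its call without ZsGreen-positive replicate 1 or 4 (0.0526 and 0.0514), without ZsGreen-negative replicate 3 (0.0957), without ZsGreen-negative replicates 3 and 4 (0.250), with limma-voom (0.0943) and with no filter on low counts (0.0579).

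**Figure D3:**
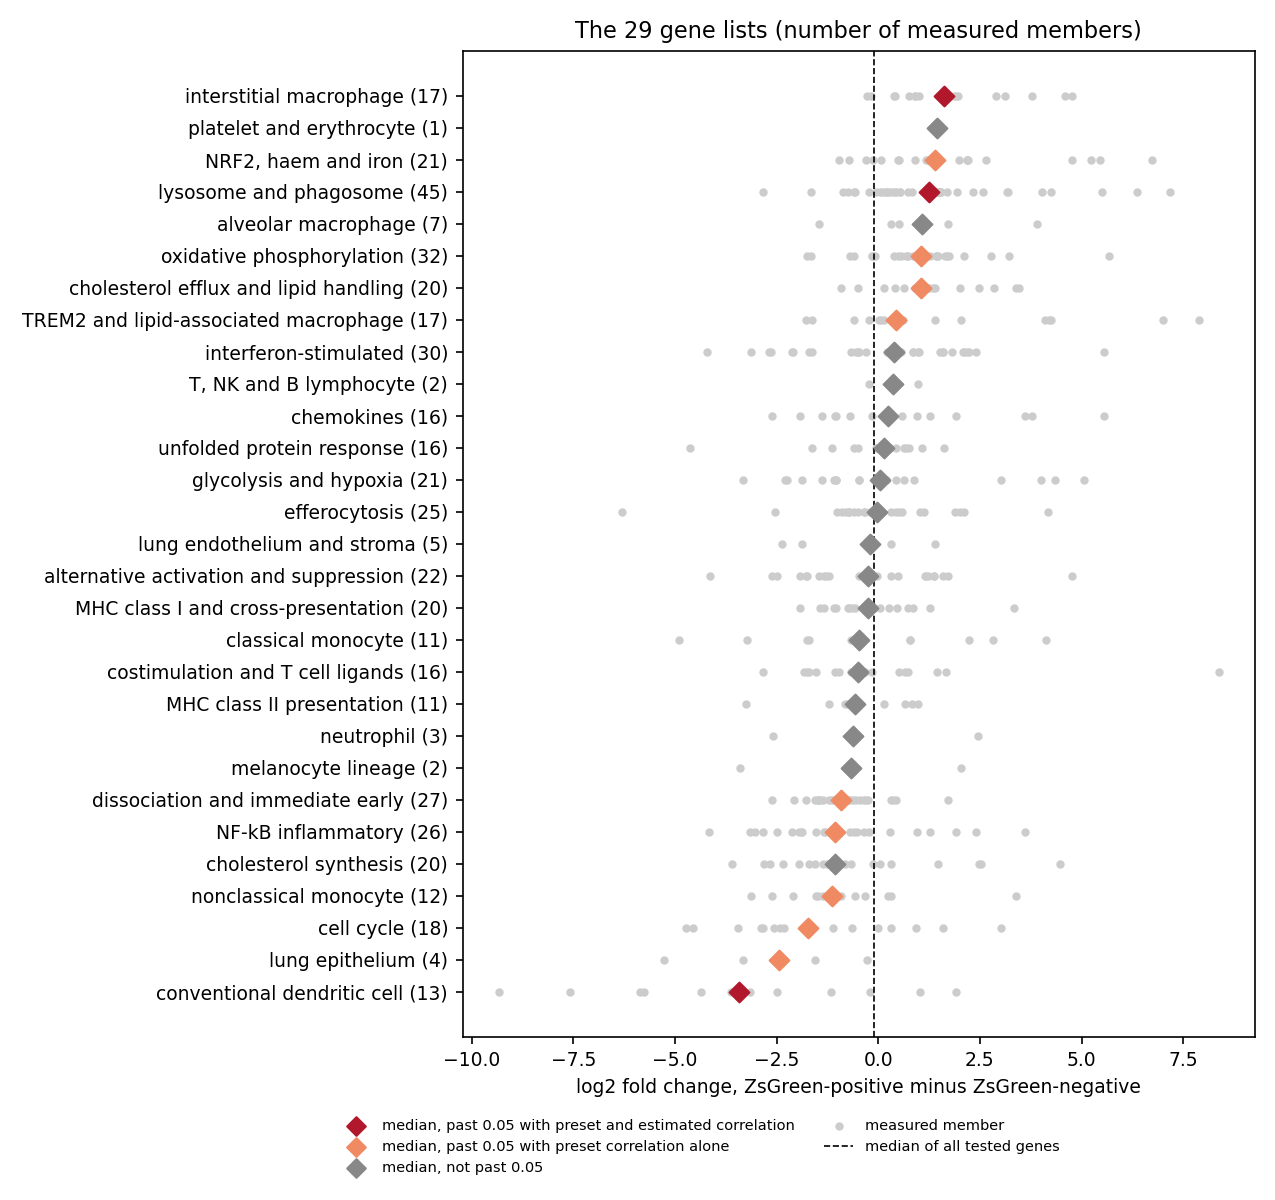
Log2 fold change, ZsGreen-positive minus ZsGreen-negative, of each measured member (small points) and the median (diamonds) of the 29 gene lists, with the number of measured members in brackets. Diamond colours give the camera result, and the dashed line marks the median of all tested genes (-0.11). Camera compared log2 CPM of the members with that of the other tested genes, so the line is not its reference. The 3 dark red medians, at 1.62, 1.24 and -3.41, belong to the lists that passed with the preset and the estimated correlation.

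The other 17 lists did not pass. MHC class II presentation genes had a median log2 fold change of -0.57 over 11 members (camera adjusted p = 0.0781); Cd74, the invariant chain gene, averaged 3480.0 ± 377 against 6082 ± 2523 CPM, and H2-Aa 3415 ± 407 against 5699 ± 1941 (adjusted p = 0.516 and 0.544). That list passed without any 1 of ZsGreen-positive replicates 2, 3 and 4 or ZsGreen-negative replicates 2 and 3, with adjusted p of 0.0317, 0.0215, 0.0241, 0.0398 and 0.0365, and with limma-voom (0.00817) and no filter on low counts (0.0247). It did not pass with DESeq2 (0.314), an estimated correlation (0.380), fry (0.238) or without ZsGreen-negative replicates 3 and 4 (0.219). With library size alone its median was -0.04 (camera adjusted p = 0.205). Classical monocyte genes had an adjusted p of 0.214 and passed without ZsGreen-positive replicate 1 (0.0271) and in replicates 2 to 4 alone (0.0491); Fn1 averaged 303 ± 116 against 1029 ± 532 and S100a4 91.4 ± 30.5 against 295 ± 99.2 CPM (adjusted p = 0.288 and 0.326). Cholesterol synthesis genes had an adjusted p of 0.0781 and passed without ZsGreen-negative replicate 3 (0.0271), without ZsGreen-negative replicates 3 and 4 (0.0392), with library size alone (0.0407) and with limma-voom (0.0285). Over 22 alternatives the MHC class II list passed in 7, the classical monocyte list in 2 and the cholesterol synthesis list in 4. Of the 35 genes on the efferocytosis list, written for the uptake of dead cells, 25 were measured, 12 with a fold above 0 and 13 below (camera adjusted p = 0.737). That list holds the Fc receptor genes Fcgr2b, Fcgr3 and Fcgr4 and leaves out Mertk, which stands on the interstitial macrophage list. Its result therefore covers the measured members and not dead-cell uptake as a whole. Interferon-stimulated genes had a median of 0.40 over 30 members (0.220; 0.0384 with no filter on low counts), and Cxcl9, a chemokine gene among them, averaged 329 ± 142 against 7.05 ± 11.8 CPM (adjusted p = 0.189). Without ZsGreen-negative replicate 1, where it stood at 24.7 CPM, Cxcl9 passed (log2 fold change 8.19, adjusted p = 0.00243). It also passed with all 8 libraries in DESeq2 (adjusted p = 0.00157) and in edgeR with replicate 1 as a term (0.0335).

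The remaining lists had camera adjusted p of 0.140 for alternative activation and suppression, which held Ccl22 at 24.5 ± 9.08 against 150 ± 71.2 CPM (adjusted p = 0.293), 0.317 for platelet and erythrocyte and 0.338 for alveolar macrophage genes. They were 0.526 for costimulation and T cell ligands, 0.557 for T, NK and B lymphocyte and for lung endothelium and stroma genes, 0.564 for MHC class I and cross-presentation, 0.737 for glycolysis and hypoxia and for the unfolded protein response, 0.774 for chemokines and 0.910 for neutrophil genes. Vcam1 was the 1 member of the costimulation list past the threshold over all genes. The 12 passing lists kept the sign of their median under TMM, RLE and upper-quartile scaling and with library size alone.

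Transcripts of the melanocyte lineage were rare in both groups. They made up 0.00596% ± 0.00283 of the counts in ZsGreen-positive and 0.00270% ± 0.00239 in ZsGreen-negative libraries (SD, n = 4 each), a difference of 0.00326 percentage points that did not pass (exact two-sided permutation p = 0.143, Benjamini-Hochberg adjusted p = 0.294 over 8 library measures; the smallest p that 70 arrangements allow is 0.0286). The pigment genes Pmel, Dct, Tyr, Tyrp1 and Mlana had 0 counts in all 8 libraries, with limits of 0.0502 to 0.293 CPM. In 7 libraries between 80.9% and 100% of the melanocyte lineage counts belonged to Mitf, a transcription factor gene that macrophages also express, at 43.3 ± 18.2 CPM in ZsGreen-positive and 10.5 ± 12.9 in ZsGreen-negative libraries (adjusted p = 0.748), the latter 4.70 CPM without replicate 2. In ZsGreen-negative replicate 3 Mitf took 0.128% of them. As a list of 2 tested members, melanocyte lineage genes had a camera adjusted p of 0.564 in the upward direction, while their median log2 fold change was -0.68.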

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

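The test of depth for the heat shock pattern, the test of a different mix of cells and the fits without ZsGreen-negative replicates 3 and 4 or without the replicate 1 libraries were chosen only after the data were seen. Grouping by chance was argued against for the 5 genes that edgeR called. Of the 35 ways to divide the 8 libraries into 4 and 4, only 1, the real one, gave as many. The other 34 gave 0 each (between 316 and 654 genes at an unadjusted p below 0.05, against 770). For the 12 gene lists too, 1 of 35 splits gave as many, with 9 lists in the highest other split. A share of 1 in 35 is the lowest that these splits allow, so chance is not excluded for the genes or the lists. For the 519 DESeq2 genes chance was not argued against. There 2 of 35 splits gave as many, and the split that exchanged ZsGreen-positive replicate 3 for ZsGreen-negative replicate 1 gave 535. The other splits gave at least 128 DESeq2 genes.

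The lower dendritic cell genes and higher interstitial macrophage genes are the first pattern. Low complexity of ZsGreen-negative replicates 3 and 4 as its whole cause is argued against by the lists' adjusted p without those libraries, 1.27e-05 and 4.06e-07. The heat shock difference between replicate 1 and the rest is argued against likewise, by 4.60e-09 and 0.000436 in replicates 2 to 4 alone. A different mix of macrophages and dendritic cells in the gates and a change of state within one kind of cell cannot be told apart: 11 of 13 measured dendritic cell genes had a fold below 0, which both predict, and bulk counts do not separate them. Uptake of tumour material, read in the sort from ZsGreen fluorescence, stays open as a biological explanation and may act through either route.

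The second pattern is that 396 genes lay higher in all 4 ZsGreen-positive libraries and 217 lay lower, against 132 expected by chance in each direction (2.86% over both directions together). At an unadjusted edgeR p below 0.05 the balance ran the other way, with 294 genes higher and 476 lower. Of the non-overlapping genes, the share that is higher, 64.6%, is not unusual, since 15 of the 70 arrangements of the libraries gave a share as high. Without ZsGreen-negative replicates 3 and 4 the share was 55.1%, with a binomial interval of 52.7% to 57.5% that treats genes as independent; the other splits of those 6 libraries reached 54.7%, and 15 splits are too few for a share under 0.05, so loss of genes in the 2 libraries and a real excess with tumour uptake cannot be told apart by that test. Of 869 genes higher in the 4 ZsGreen-positive libraries than in ZsGreen-negative replicates 2 to 4, 45.6% (interval 42.2% to 48.9%) also lay below all of them in ZsGreen-negative replicate 1. Of 417 lower genes, 52.0% (interval 47.1% to 56.9%) lay above. The first interval lies below the 50% that chance gives and the second holds it. Both treat genes as independent and rest on 1 library, so gene loss and chance cannot be told apart here. The lower genes are not free of gene loss either, since it can raise the scaled levels of the genes kept. TMM factors were 0.499 and 0.716 in ZsGreen-negative replicates 3 and 4 and between 1.07 and 1.32 in the ZsGreen-positive libraries.

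The third pattern is the low level of heat shock transcripts in both replicate 1 libraries. Hspa1a stood at 106.5 and 108.9 CPM there and between 2761 and 9646 CPM in the other 6 libraries, Hspa1b, a near-identical copy whose reads may be shared with it, at 37.0 and 55.0 against 1383 to 7376, and Hsp90aa1 at 45.9 and 64.1 against 189.8 to 946. Depth is argued against, because the 2 libraries have the highest and the lowest totals, a ratio of 5.85; so are shared reads, since 13 other heat shock genes had a median log2 difference of -1.44 and 12 of them lay below 0. A weaker dissociation response of every kind is argued against by a median of 0.15 over 16 immediate early genes. None of them was below -1 in the mean of both groups' differences. In the ZsGreen-negative group alone, Atf3 (-2.05), Egr1 (-1.58), Nr4a1 (-1.11) and Jun (-1.10) were below -1. Ier3 (6.03), Jund (2.67), Nr4a2 (1.03) and Fosb (1.02) were above 1 there. A difference in handling between replicate 1 and the rest stays open, and the design names no biological group that could account for it.

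Single libraries lay far from the other 3 of their group in 27 of 154 group checks of 77 measures, where chance marks about 5%; the checks overlap in libraries and low levels are skewed, so these are values to look at and not a count of errors. In ZsGreen-negative replicate 3, Stat5a stood at 2084 CPM, Scgb1a1 at 889.5, Mcemp1 at 692.4, Top2a at 577.5, Eno3 at 182.9 and Igf1 at 51.8. In ZsGreen-negative replicate 1, Ctsd stood at 120.5 CPM, Cxcl9 at 24.71, Cd38 at 3.837 and Spic at 1.381, each the highest of its group. By Spearman correlation ZsGreen-negative replicate 1 lay closer to ZsGreen-positive replicates 1 and 2 (0.733 and 0.681) than to any library of its own group (at most 0.664). ZsGreen-negative replicate 2 was highest for Btla at 239.8, Klrb1c at 30.58, Xist at 11.05 and Acp5 at 2.791 CPM, and ZsGreen-negative replicate 4 for Siglecf at 0.0547, which is 1 count against 0 in the other 3.

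In ZsGreen-positive replicate 1, Zfp36 was highest at 743.1 CPM and Btla at 6.21. Replicate 2 was highest for Flt3 at 0.8995 and Xist at 0.1241 and lowest for Tiam1 at 9.491 CPM. Replicate 3 was highest for Hmox1 at 136.7, Klrb1c at 18.14 and Napsa, a surfactant-processing protease gene, at 15.95, and lowest for Cd93 at 672.6. Replicate 4 was highest for Slc40a1 at 102.2 and Siglecf at 18.5 and lowest for Abcg1 at 57.66 CPM.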

How the results depend on the processing

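The settings that left out replicate 1 or ZsGreen-negative replicates 3 and 4, added replicate 1 as a term, used robust dispersions or dropped mitochondrial genes were chosen after seeing the data. Against 5 genes with edgeR as designed, DESeq2 called 519 and limma-voom 10; of the DESeq2 genes, 271 were tested by edgeR and 256 had an unadjusted edgeR p below 0.05. RLE scaling gave 3 genes, no filter on low counts 237 (38 higher and 199 lower, from 19284 tested), a threshold of 0.01 gave 2 and glmTreat 3; the last 2 are stricter by construction, and the cause of the other differences was not tested. Without ZsGreen-negative replicates 3 and 4, 8 genes passed, 4 of them shared with the 5. Leaving out each library in turn gave 2 to 7 genes and 10 to 13 lists; 2 genes passed without ZsGreen-positive replicate 1, 2 or 4 or ZsGreen-negative replicate 4, and 3 without ZsGreen-negative replicate 2. Upper-quartile and library-size scaling, robust dispersions and the replicate 1 term each gave 7 genes, and the 1 CPM filter, replicates 2 to 4 alone and dropping mitochondrial genes 5. Over 22 alternatives Cd209a passed in 22, Vcam1 in 21, Kit in 15, Ctsb in 12 and Mfsd6 in 11, each with an unchanged sign; Vcam1 missed the threshold with limma-voom (adjusted p = 0.0580). Of 12 lists, 3 passed with an estimated correlation and 5 with fry, which tests one-way movement of a list alone. In simulations of independent genes the estimated correlation found a shifted list in 2 of 10 runs and the preset in 10 of 10. In the 34 other splits of the real libraries the preset called up to 9 lists (median 0) and the estimated correlation 0. All of those splits with a list called kept 3 libraries of each group together. They held part of the real difference, so these counts are not a rate of false calls. Other settings gave 11 to 13 lists, except 8 without ZsGreen-negative replicates 3 and 4. The dendritic cell, interstitial macrophage and lysosome lists passed in 22 of 22, with adjusted p up to 0.00795, 0.0306 and 0.0306. With the replicate number as a block (replicate block), edgeR called 15 genes and 11 lists: Mki67 and Ctsd (adjusted p = 0.00267 each), Mertk and Cxcl9 (0.00595 each) and Igf1 (0.0244) passed, and the nonclassical monocyte list did not (0.0817). Same-numbered libraries of both groups deviated together by correlations of 0.08, 0.02, 0.02 and -0.01 (replicates 1 to 4), below 0.1. Replicates 1 and 2 of each group correlated best with the other group under their own number, and replicates 3 and 4 under another. The numbers were therefore not read as pairs in the main fit. Heat shock transcripts did divide both groups by replicate number, so shared animals or handling are not excluded. The melanocyte and mitochondrial shares did not pass 0.05 in any alternative run, and the 5 pigment genes alone gave a difference of 0. At this spread and depth, edgeR rarely detects log2 folds of 2, so a gene that did not pass may still differ by that much.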

Other observations

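Of the tests in this part, the comparison of haem and iron with antioxidant genes was chosen only after the result of their shared list was seen. The genes of the next 2 paragraphs lie outside the fixed lists and were chosen after their values were seen, from those whose groups did not overlap, and none passed the edgeR threshold over all genes.

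Several genes known from macrophages lay higher in 4 of 4 ZsGreen-positive libraries. Mpeg1, which encodes the pore-forming protein perforin-2, averaged 1792 ± 427 CPM in ZsGreen-positive against 524 ± 153 in ZsGreen-negative libraries (SD, n = 4 each; log2 fold change 1.77, edgeR adjusted p = 0.189). Cd93, a membrane lectin gene, averaged 757 ± 57.0 against 168 ± 22.5 CPM (log2 fold change 2.17, edgeR adjusted p = 0.106). Selenop, which encodes a selenium transport protein, averaged 1221 ± 230 against 381 ± 204 CPM, and the transcription factor gene Maf 276 ± 39.2 against 81.1 ± 55.6. Cmklr1, the chemerin receptor gene, averaged 105 ± 45.4 against 15.9 ± 15.1 CPM, the complement gene C3 83.2 ± 45.3 against 4.45 ± 5.87, and Cd38, which encodes an NAD-consuming enzyme of the cell surface, 46.5 ± 13.99 against 1.22 ± 1.77. Without ZsGreen-negative replicate 1 the ZsGreen-negative means of Cmklr1, C3 and Cd38 were 9.04, 1.56 and 0.348 CPM.

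Other genes lay lower in 4 of 4 ZsGreen-positive libraries. Bcl11a and Cbfa2t3, which encode transcriptional regulators of blood cell development, averaged 4.04 ± 3.62 against 115 ± 82.0 and 21.3 ± 3.86 against 178 ± 141 CPM (log2 fold changes -4.83 and -3.06, edgeR adjusted p = 0.252 and 0.273). P2ry10, a lipid receptor gene, averaged 1.33 ± 1.06 against 80.9 ± 68.5 CPM, and Tiam1, which encodes an activator of the GTPase Rac, 27.9 ± 12.4 against 305 ± 181. Ifitm3, an antiviral membrane protein gene, averaged 46.7 ± 24.7 against 416 ± 428 CPM and Mcemp1 4.33 ± 3.89 against 244 ± 299. Stat5a averaged 13.9 ± 6.03 against 556 ± 1019 CPM. Without ZsGreen-negative replicate 3 the ZsGreen-negative means of Stat5a, Ifitm3, Mcemp1, P2ry10 and Cbfa2t3 were 46.4, 206, 94.4, 53.1 and 118 CPM. That of Bcl11a was 75.5 CPM without replicate 4, and the ZsGreen-positive means of Bcl11a and Mcemp1 were 2.41 CPM without replicate 4 and 2.67 CPM without replicate 1. The cytoskeletal genes Ahnak and Vim averaged 1126 ± 163 against 2870.1 ± 549 and 1330 ± 282 against 3185 ± 2014 CPM.

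A hypothesis was that the dendritic cell difference reaches genes outside the fixed lists. Core dendritic cell and core macrophage genes, none of them on a fixed list, were chosen after those lists had been tested and before their own values were seen. In both core lists, 0 genes had groups that did not overlap. Of 14 measured dendritic cell core genes, 11 had a fold below 0, with a median log2 fold change of -0.47. The camera p was 0.00441, and 0.0232 with an estimated correlation, which goes with the hypothesis. The p of the core lists were not adjusted for the number of lists tested. Camera's directions are relative to the other tested genes, so this result may rest in part on their level. Of 17 measured macrophage core genes, 12 had a fold above 0, with a median of 0.75 (camera p = 0.157; p = 0.179 with an estimated correlation), so whether macrophage character differs beyond the fixed list is undecided.

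A second hypothesis was that the haem and iron members of the NRF2, haem and iron list differ more than its antioxidant members. The 9 measured haem and iron genes had a median log2 fold change of 2.18 and the 11 antioxidant genes one of 1.23. The difference of 0.95 had an exact one-sided permutation p of 0.181 over 167960 arrangements of the genes, which are not independent replicates, so the parts of the list cannot be told apart at this spread.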
